A study of Leishmania infantum with 2 samples.

How the data were processed

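RNA was measured in 2 libraries of Leishmania infantum promastigotes, the flagellated form of this parasite that lives in the sand fly gut and grows in culture. Per the labels, 1 library came from promastigotes recovered from the gut of the sand fly Phlebotomus perniciosus (sfPro), and 1 from promastigotes grown in axenic culture (acPro). Both were pools. The flies had fed 5 days earlier, through a chick skin membrane, on rabbit blood that carried late-logarithmic promastigotes. Per the labels' protocols, RNA was extracted with TRIzol and sequenced by spliced-leader RNA-seq. In this method the second cDNA strand is primed on the spliced leader, a short sequence that trypanosomatids join to the 5' end of every mRNA, which favours parasite mRNA over RNA of the fly, the blood meal and bacteria. The libraries were made with PCR and no molecular identifiers are named. The intervals below cover counting error only and treat each read as independent, so that they are too narrow where reads are PCR duplicates.

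The submitters' processing notes name FastQC, Bowtie2, SAMtools and featureCounts, without versions or roles. The genome build, the annotation and the filters are not given in the sources used here. The deposited table holds 8236 coding sequences (CDS) with an identifier and a product name, and 17 summary rows without an identifier, which were left out. Per the file headers, the first pair of columns is the raw read count of each CDS in each library. Some of these values end in 0.5, so that they were treated as estimated counts by the authors and rounded to whole numbers for every interval. A read that fits several copies of a gene could have been divided or placed among them in ways that the sources do not describe. Per the file headers, a second pair of columns holds normalized TPM, but these deposited values do not sum to the same total in both libraries, so that they were treated as a signal scaled by the authors by 1 further factor per library. The method behind that factor is not given in the sources used here. The deposited signed ratio, log2 ratio and p-value columns were treated as scores of the authors, because neither the test nor any adjustment is stated.

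The header of the deposited ratio columns gives their direction as acPro over sfPro, while their values follow the opposite direction. Of 6725 CDS with a normalized TPM of at least 10 in both libraries, 6725 had a deposited log2 ratio within 0.1 of log2 sfPro over acPro, and 380 were within 0.1 of log2 acPro over sfPro. Directions below follow the names of the count columns. Were the names of those columns the ones at fault, every direction would turn around, and nothing in the sources used here settles this.

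Library totals over CDS were 10861673 reads for sfPro and 32082181.5 reads for acPro. CDS with fewer than 20 reads over both libraries were left out (50 of 8236), which kept 8186. Libraries were scaled by TMM (edgeR 4.0.16 in R 4.3.3), with factors of 0.926 for sfPro and 1.08 for acPro. The log2 ratio of sfPro over acPro was computed with a prior of 0.5 reads in each library. Its 95% interval is the exact conditional binomial (Clopper-Pearson) interval of the ratio of both counts. The median half-width over CDS was 0.157 on the log2 scale. A CDS was called higher or lower in sfPro when the ratio was at least 2-fold and the interval excluded 1. With 1 library per group there is no replicate check, no p-value was computed, and any such interval compares these 2 libraries and not the conditions.

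A total of 43 gene lists (pathways, complexes, surface families, and markers of other parasite forms) were matched on product names with patterns written before the data were examined, as were the call, the chromosome comparison and the rule for named genes. For each of the 41 lists with at least 4 measured CDS, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. The same was done for the CDS of each of the 36 chromosomes, with the chromosome read from the gene ID. These percentiles describe the 2 libraries, and the span from the 2.5th to the 97.5th percentile is called the random range. Named genes needed at least 100 reads over both libraries. They were the 10 highest and 10 lowest ratios among CDS with a known product (at most 2 per identical product), the 3 highest and 3 lowest among hypothetical or unknown products, the 2 highest and 2 lowest members of each list, and all metacyclic markers that passed the filter. Other genes are said to be chosen after their values were seen. Tandem copies, a grouping added after the values were seen, were CDS with the same known product on a chromosome, each within 10 genes of the next (232 arrays with 569 CDS). No genome sequence was used, so that how alike the copies of an array are, and whether reads fit several of them, was not checked. A reference gene table of assembly ASM287v2 held 8081 of the 8236 identifiers as locus tags, and 8042 of 8046 compared pairs of successive identifiers lay in the same order there. Because the build of the counts is not named, the table was used for gene order only, no coordinates are printed, and genes are given by the identifier in the deposited table.

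The call was tested on simulated data for the comparison of sfPro with acPro, with counting noise only, over 8184 CDS. All 50 CDS raised and all 50 lowered by 3-fold were recovered, as were 50 and 50 at 6-fold, and 1 of 7984 unchanged CDS was called. The 95% interval held a ratio of 1 for 95.6% of unchanged CDS. Of 200 simulated lists of 30 CDS without a shift, 15 lay outside the 2.5th to 97.5th percentile, and of 20 lists shifted by 0.5 on the log2 scale, 20 lay above it. Simulated ratios with counting noise only spread less than the real ones (quartiles -0.48 and 0.49). These simulated lists thus do not show how well such a shift would be found in the real lists. Alternatives were other scalings (total counts, and the median-of-ratios factors of DESeq2 1.42.0), other filters, priors, folds and intervals, ratios centred on each chromosome, lists without large product families, unmatched random lists and list means. Counts summed over tandem copies and the normalized TPM of the authors were added after the data were examined. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.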

Results

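Promastigotes of Leishmania infantum that developed in the gut of the sand fly Phlebotomus perniciosus were compared with promastigotes of the same strain grown in axenic culture, to find which transcripts differ between the insect vector and the culture flask. Transcript abundance was measured by spliced-leader RNA-seq in 1 pooled library per group, so that no difference below has a replicate check. The sfPro library (gut-derived, day 5 after feeding) held 10861673 reads over CDS and the acPro library (cultured) 32082181.5. The median CDS had 437 reads in sfPro and 1478 in acPro. The 10 most abundant CDS took 10.3% of the sfPro reads and 8.88% of the acPro reads, and 100 CDS took 33.2% and 29.3%. In what follows, higher and lower are by the names of the count columns, sfPro against acPro. The header of the authors' deposited ratio columns names the opposite direction.

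In the gut-derived library, 29 of 46 amastin CDS, 13 of 17 surface antigen-like CDS and 18 of 28 histone CDS were at least 2-fold higher than in the cultured library, as were the HASP CDS and the summed copies of ATG8 and of paraflagellar rod protein 1D. Of 182 cytosolic ribosomal protein CDS, 64 were at least 2-fold lower, as were both copies of a P-type H-ATPase. Of 8186 CDS compared, 861 (10.5%) were at least 2-fold higher in sfPro and 541 (6.61%) at least 2-fold lower, with a 95% counting interval that excluded a ratio of 1. The higher side reached further: 126 CDS were at least 4-fold higher against 21 at least 4-fold lower, and 31 were at least 8-fold higher against 1 at least 8-fold lower. Calls of CDS with hypothetical or unknown products made up 345 of the higher and 208 of the lower CDS. The balance depended on the scaling. With total-count scaling, which moved the median log2 ratio of all CDS from -0.02 to -0.24, 547 CDS were higher and 1013 lower, so that higher CDS were 35.1% of the calls instead of 61.4%.

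**Figure D1:**
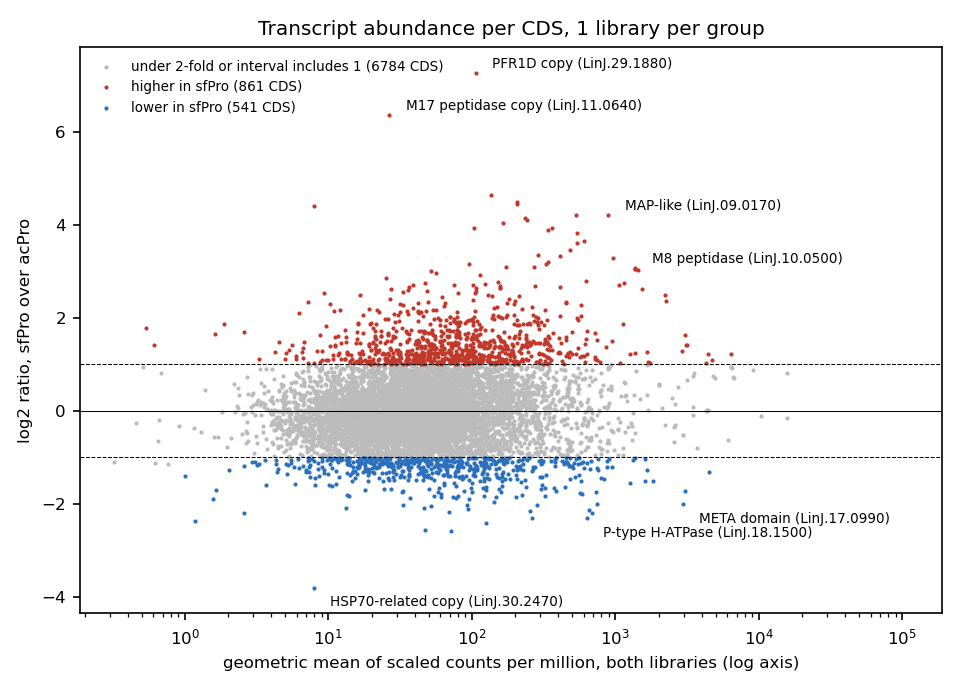
Log2 ratio of sfPro over acPro of each of 8186 CDS (vertical axis) against the geometric mean of the scaled CPM of both libraries (horizontal log axis), with 1 library per group. Red points are the 861 CDS called higher in sfPro and blue points the 541 called lower, dashed lines mark 2-fold, and the highest point is 1 copy of paraflagellar rod protein 1D at 7.27.

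The highest ratio belonged to a copy of paraflagellar rod protein 1D (LinJ.29.1880), part of the lattice that runs beside the axoneme of the flagellum, with 13363 reads in sfPro and 297 in acPro (log2 ratio 7.27, 95% interval 7.11 to 7.45). Its neighbouring copy LinJ.29.1890 was 1.88 higher on the log2 scale, and both copies summed gave 3.73. A pair of microtubule associated protein-like CDS (LinJ.09.0170 and LinJ.09.0190) were each higher by 4.22, with 4.20 for the sum of their 3 copies. Copies of ATG8, a ubiquitin-like protein of autophagosome membranes, were at 4.64 (LinJ.19.0850) and 4.05 (LinJ.19.0820), and 3.78 for the sum of the 4 copies on chromosome 19. A 3-hydroxyisobutyryl-coenzyme A hydrolase-like CDS (LinJ.32.3820) was at 3.94 (array sum 3.92). A DEAD-box helicase-like fragment (LinJ.27.2510), with 371 reads in sfPro and 60 in acPro, was at 4.40 (4.02 to 4.83).

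For 2 other extreme genes the sum over the tandem copies did not reach 2-fold. The value of a single copy is uncertain if its reads also fit the other copies, which was not checked by sequence. A copy of an M17 family metallo-peptidase (LinJ.11.0640) was at 6.37 with 2436 against 101 reads, its neighbour LinJ.11.0630 at -1.51, and their sum at 0.59. Copies of nucleoside transporter 1, which imports nucleosides across the plasma membrane, were at 4.45 (LinJ.15.1250) and 4.15 (LinJ.15.1230), while LinJ.15.1260 had 28358 reads in sfPro and 244653 in acPro, a log2 ratio of -1.32. The 4 copies summed gave -0.32. On the low side, a copy of heat shock 70-related protein 1, a mitochondrial chaperone (LinJ.30.2470), had 21 reads in sfPro and 1032 in acPro (-3.80, interval -4.53 to -3.21). Its array summed to -0.18, but this copy held few of the array's reads, so that the sum says little about it.

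**Figure D2:**
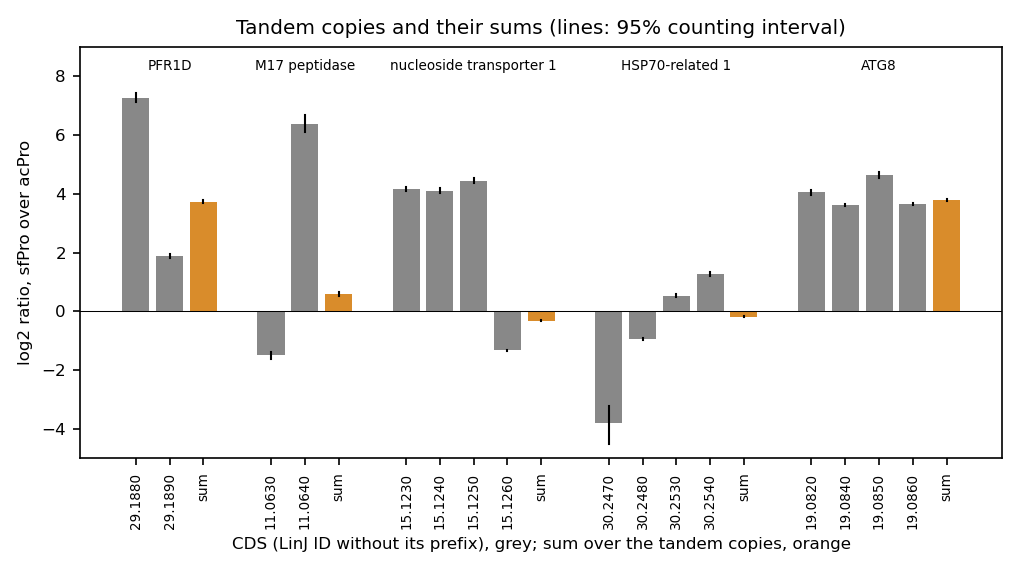
Log2 ratio of sfPro over acPro of each tandem copy (grey bars) and of the counts summed over the copies (orange bars) for 5 named genes, with 95% counting intervals as lines and 1 library per group. The sums of PFR1D and ATG8 stay at 3.73 and 3.78, while those of the M17 peptidase, nucleoside transporter 1 and HSP70-related protein 1 lie at 0.59, -0.32 and -0.18.

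Among the lowest ratios, both copies of the P-type H-ATPase, a plasma membrane proton pump, were at -2.30 (LinJ.18.1500) and -2.14 (LinJ.18.1510), with 2860 reads in sfPro and 48680 in acPro for the first. Both CDS of 60S ribosomal protein L14 were at -2.29 (LinJ.22.1370) and -2.15 (LinJ.22.1410). A kinesin (LinJ.22.0780) was at -2.59 (-2.76 to -2.42), octanoyltransferase (LinJ.36.3230), which acts in the lipoylation of mitochondrial enzymes, at -2.57, and phosphatidylinositol 4-kinase alpha (LinJ.29.1550) at -2.41. Cytochrome c oxidase assembly protein PET191 (LinJ.34.3720) was at -2.08. The ratio of a C56 family cysteine peptidase (LinJ.35.3950) rested on 5 and 97 reads, and its interval ran from -4.15 to -1.22 around -2.36. Of the CDS without a known function, LinJ.04.0160 (4.50), LinJ.20.1270 (3.35) and LinJ.04.1090 (3.17) were the highest, and LinJ.15.1590 (-2.20), LinJ.36.7250 (-2.19) and LinJ.22.1140 (-2.17) the lowest.

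Genes known as markers of metacyclic promastigotes, the infective form, went both ways. Of 7 CDS, 4 were at least 2-fold higher in sfPro and 1 at least 2-fold lower, and the median was 2.01 (random range -0.83 to 1.03). As 6 of the 7 lie in tandem arrays, counts were also summed over copies, which gave a median of 1.36 (percentile 98.4), and the list mean was 1.13 (percentile 98.3). Hydrophilic acylated surface protein B (LinJ.23.1220) was at 2.34 and both copies of hydrophilic acylated surface protein A at 2.33 (LinJ.23.1200) and 2.01 (LinJ.23.1240). The copies of SHERP, a small protein of the endoplasmic reticulum, were under 2-fold, at 0.59 (LinJ.23.1230) and 0.56 (LinJ.23.1210). The META domain CDS differed in direction. LinJ.17.0970 was at 2.07, and LinJ.17.0990, the more abundant with 14785 reads in sfPro and 203922.5 in acPro, was at -2.0, which put their sum at -1.67.

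Of 46 amastin CDS, surface glycoproteins known best from the intracellular amastigote, 29 were at least 2-fold higher and 1 lower (LinJ.30.0930, -1.47), with a median of 1.24 against a random range of -0.18 to 0.41. The highest were LinJ.08.1320 (3.16) and LinJ.08.0710 (2.77). In total 36 of these 46 CDS lie in tandem arrays and their reads could have been divided between copies. Summed over the copies the median was 1.02. Without product families of 5 or more CDS it was 1.04, within the random range of the smaller list (percentile 97.3). Of 17 surface antigen-like CDS, 13 were higher and none lower, with a median of 1.19 (random range -0.38 to 0.56), led by LinJ.05.0900 (3.34) and LinJ.04.0190 (3.20). The gp63 list, the surface zinc metalloproteases known as leishmanolysins, held 3 CDS, of which LinJ.10.0490 was higher (1.47), and LinJ.28.0600 (0.85) and LinJ.28.0610 (0.66) were under 2-fold. Its neighbours LinJ.10.0500 to LinJ.10.0530 carry the product name of the M8 metallo-peptidase family, to which leishmanolysin belongs, and were chosen after their values were seen. These 4 ratios lay between 3.02 and 3.08, and their sum held 160625 reads in sfPro and 66958 in acPro, 8.27-fold higher after scaling. The remaining CDS with that product name, LinJ.31.2040 on another chromosome, was at -0.09. The A2 protein (LinJ.22.0670), known from amastigotes, was at 0.54.

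Of 28 histone CDS, 18 were at least 2-fold higher and none lower, with a median of 1.22 (random range -0.34 to 0.53). Histone H4 copies LinJ.25.2560 (2.76) and LinJ.21.0020 (2.54) were the highest. Histone H3 LinJ.10.1050, the most abundant member named, with 149987 and 575911.5 reads, was at -0.16, and another H4 copy, LinJ.35.1320, at -0.28. The list of 89 DNA replication and cell cycle genes had 4 higher and 4 lower members and a median of -0.02, inside its random range of -0.20 to 0.17. A list of 37 genes conserved so deeply that reads of other organisms might be counted to them had a median of 0.46 at the 96.7th percentile, and the 99.5th with tandem copies summed. Its 14 histones had a median of 1.32 and its other 23 CDS 0.01, a division made after the values were seen.

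Of 182 cytosolic ribosomal protein CDS, 64 were at least 2-fold lower and 4 higher, and 150 lay below 0. Their median of -0.76 was below every random list (random range -0.02 to 0.27). The large and small subunits had medians of -0.67 over 113 CDS and -0.84 over 69. The L14 copies named above were its lowest members, and a ribosomal protein L3-like CDS (LinJ.29.0030, 1.29) and 60S acidic ribosomal protein P2 (LinJ.03.0410, 1.19) its highest. The P2 CDS is 1 of 2 tandem copies, and their sum was under 2-fold, at 0.92. Splicing genes had a lower median too (-0.34, percentile 1.75), with 5 of 36 CDS lower, such as Isy1-like (LinJ.07.0020, -1.42), and 4 higher, such as pre-mRNA-splicing factor 38 (LinJ.20.1170, 1.79). The splicing list moved inside the random range once ratios were centred on each chromosome (percentile 4.98).

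The median shift was smaller in 3 other lists above their random ranges. Of 118 flagellar and axonemal CDS, 13 were higher and 2 lower. The median was 0.21 (percentile 98.7), and it changed sign with total-count scaling, to -0.01. Besides paraflagellar rod protein 1D, a paraflagellar rod component (LinJ.09.1390) was at 2.47, and the 2 members called lower were the dynein heavy chains LinJ.36.1010 (-1.19) and LinJ.28.0650 (-1.04). The 14 paraflagellar rod CDS had 6 higher and none lower and the 46 dynein CDS 3 higher and 2 lower, a division made after the values were seen, with medians of 0.74 and 0.01. Of 28 purine and pterin transporters, 8 were higher and 2 lower, with a median of 0.52 (percentile 99.8), 0.30 with total-count scaling and a mean of 0.84, but centring on chromosomes put the list at the 97.1th percentile, within the range. The list of 30 phosphoglycan synthesis CDS, which build the lipophosphoglycan coat, had a median of 0.41 (percentile 98.9), or 0.19 with total-count scaling, with 4 higher and 2 lower. Phosphoglycan beta 1,3 galactosyltransferase copies LinJ.02.0150 and LinJ.02.0140 were at 1.42 and 1.25, and a UDP-galactose transporter (LinJ.22.0830) at -1.35. That list was within the random range with tandem copies summed (0.16, percentile 76.7).

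**Figure D3:**
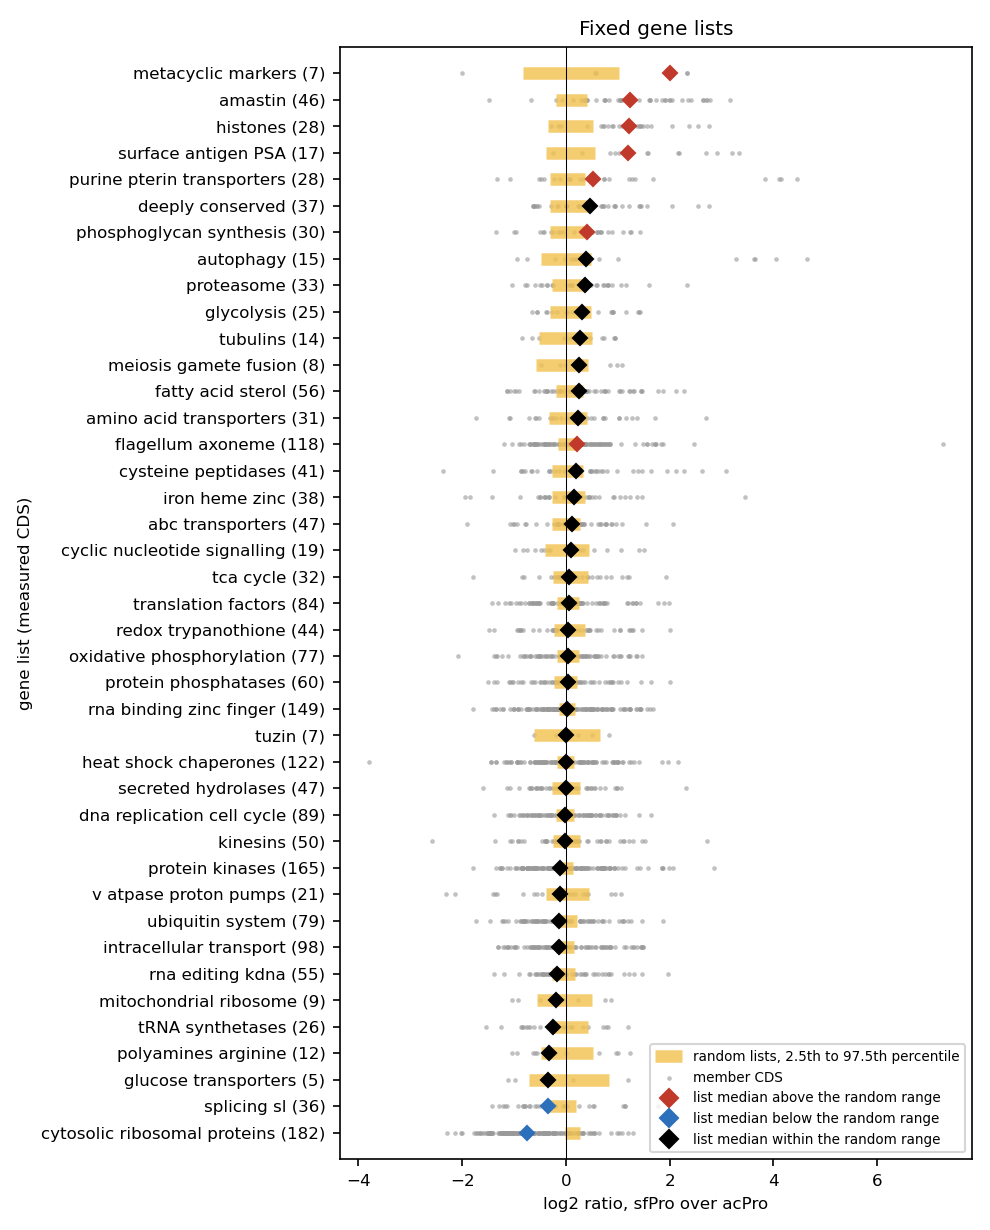
Log2 ratio of sfPro over acPro of the member CDS (grey points) and the median (diamond) of each of 41 gene lists, with the number of measured CDS in parentheses and the random range over 10000 expression-matched random lists as yellow bars. The medians of 7 lists lie above the random range, led by the metacyclic markers at 2.01, and 2 lie below it, the cytosolic ribosomal proteins at -0.76 and the splicing genes at -0.34, while the flagellar median of 0.21 turns to -0.01 with total-count scaling.

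Leishmania genes stand in long arrays transcribed in 1 direction, so that ratios were also compared by chromosome. Of 36 chromosomes, 11 had a median above and 10 a median below the random range. The highest were chromosome 2 (median log2 ratio 0.73 over 73 CDS, 63 of them above 0), chromosome 8 (0.69 over 121 CDS) and chromosome 5 (0.63 over 121 CDS). The lowest were chromosome 22 (-0.60 over 163 CDS, 140 of them below 0), chromosome 15 (-0.43 over 163 CDS) and chromosome 1 (-0.40 over 85 CDS). On chromosome 22, 41 CDS were called lower, both L14 copies and the kinesin LinJ.22.0780 among them, and 1 was called higher. On chromosome 8, 40 were called higher and none lower. The large chromosomes 35 and 36 were at -0.22 and -0.21. Chromosome 3 changed sign with total-count scaling, from 0.17 to -0.05. With ratios centred on each chromosome's median, 768 CDS were higher and 428 lower.

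**Figure D4:**
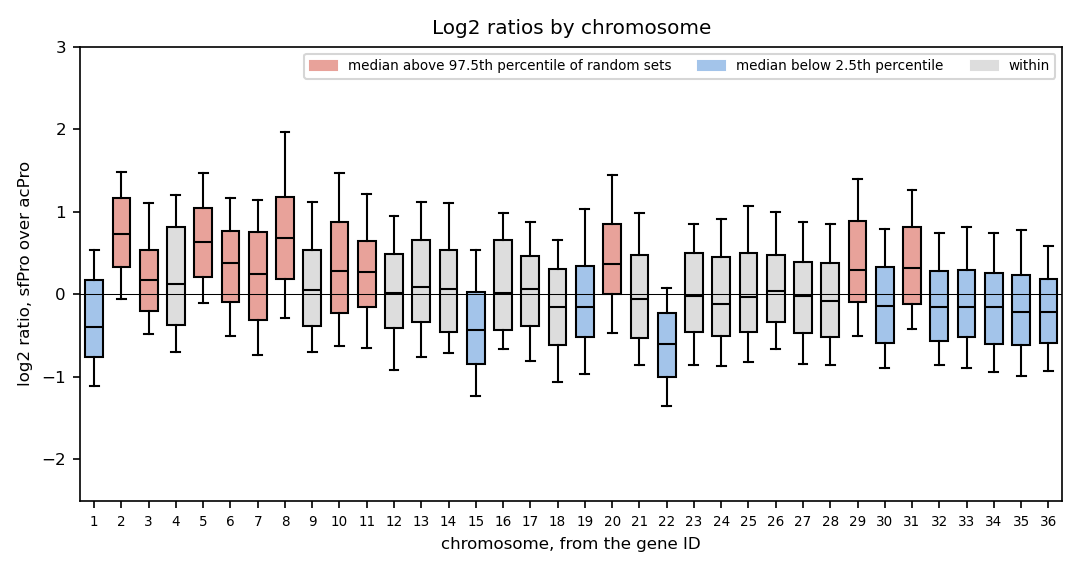
Log2 ratio of sfPro over acPro by chromosome, with boxes from the lower to the upper quartile of CDS, the median as a line, and whiskers at the 10th and 90th percentiles. Red boxes mark the 11 chromosomes with a median above the random range and blue boxes the 10 below it, of which chromosome 2 (0.73) is the highest and chromosome 22 (-0.60) the lowest, and chromosome 3 (0.17) turns to -0.05 with total-count scaling.

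The authors' deposited table carries its own log2 ratio and p-value for each CDS, from a test that is not stated and that can only compare these libraries, not the conditions. In the authors' deposited table, 1129 CDS had a p under 0.05, of which 569 had a log2 ratio of at least 1 and 224 of at most -1. Of 7731 CDS that passed the read filter and had a deposited ratio other than 0, 7720 had the same sign as the recomputed sfPro over acPro ratio. The authors' deposited table gives a log2 ratio of 7.3 for LinJ.29.1880, 4.2 for LinJ.09.0170, 2.4 for LinJ.23.1220, -2.0 for LinJ.17.0990 and -2.3 for LinJ.18.1500. Of the CDS called here, 540 of the 861 higher and 216 of the 541 lower had a p under 0.05 in the authors' deposited table. The overlap followed abundance. With the CDS divided by mean expression into 4 classes of equal size, 6 of 207 called CDS in the lowest class and 548 of 604 (90.7%) in the highest had a deposited p under 0.05.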

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

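Counts summed over tandem copies and the authors' normalized TPM were chosen as settings after the data were examined. With total-count scaling 547 CDS were higher and 1013 lower, because the scaling shifts all ratios down, and it reversed the medians of the flagellar list (-0.013) and of chromosome 3 (-0.051). Other thresholds moved the counts by construction: 1772 and 1644 CDS at 1.5-fold, 126 and 21 at 4-fold, and 301 lower with the whole interval beyond 2-fold (657 higher). The other settings gave 731 to 886 higher and 428 to 542 lower CDS, each within 1.5 times of 861 and 541. List means put 14 lists outside the random range instead of 9. For the other settings it was 8 to 12 lists, and 21 or 22 chromosomes. Without product families of 5 or more CDS the amastin median was 1.04 at the 97.3th percentile and the phosphoglycan median 0.22 at the 86.3th, both within the random range, while amino acid transporters lay above it (0.72, percentile 99.6). The surface antigen list then held fewer than 4 CDS and could not be placed against the random range. Splicing genes were within it at percentile 3.35 with unmatched random lists. The ubiquitin system list fell below the range with at least 100 reads (percentile 2.16), without those families (0.10) and by its mean (1.52), and the proteasome list lay above it with centring on chromosomes (97.8) and unmatched lists (99.4). By their means, autophagy (1.32, percentile 100), cysteine peptidases (97.8) and deeply conserved genes (97.7) lay above the range, and aminoacyl-tRNA synthetases (1.82) and proton pumps (0.90) below it, while phosphoglycan genes (87.1) lay within it. Unmatched lists put glycolysis (97.55), fatty acid and sterol genes (98.8) and deeply conserved genes (99.95) above it, and the authors' normalized TPM cysteine peptidases (99.0). Causes of these list changes were not tested. Of 182 named ratios, 157 moved beyond their counting interval with total-count scaling, 4 with DESeq2's factors and 12 with the authors' normalized TPM. The 1 that changed sign was glucose transporter 2 (LinJ.36.6550), from 0.14 to -0.08 with total-count scaling, which also turned the signs of 12 list medians and 8 chromosome medians that lay within their random ranges. No paired analysis was possible because each group has 1 library. Alternatives planned for tables of normalized values alone or with replicates did not apply. Depth limits CDS with few reads, since 32 CDS had no read in sfPro and 21 none in acPro.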

Other observations

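Tests of tandem copies, of the share of metacyclic forms, of windows for chromosome 1 apart from the others, and of shifted chromosomes with total-count scaling were chosen after the results were seen. Several transporters not yet described stood far from 0. An iron/zinc transporter-like CDS (LinJ.31.3190) was at 3.46, with 3.30 for its array, while zinc transporters 3A (LinJ.28.2050) and 3B (LinJ.28.2060) were at -1.95 and -1.84. Amino acid permease 3 (LinJ.31.0910) was at 2.71 and amino acid permease 24 (LinJ.10.0770) at 1.72, against -1.73 for the permease LinJ.35.4480, and the 31 amino acid transporters had a median of 0.24 (percentile 87.2), or 0.72 (percentile 99.6) without product families of 5 or more CDS. Glucose transporter 3 (LinJ.36.6540) was at 1.20 and glucose transporter 1 (LinJ.36.6560) at -0.99, while the abundant glucose transporter 2 (LinJ.36.6550, 27430 and 85607 reads) was at 0.14, or -0.08 with total-count scaling. ABC transporters had 3 higher and 3 lower of 47. In energy metabolism the medians were 0.31 for glycolysis (4 higher of 25, both glycosomal glyceraldehyde 3-phosphate dehydrogenase copies, LinJ.30.2990 and LinJ.30.3000, at 1.42), 0.06 for the TCA cycle (succinate dehydrogenase LinJ.15.1050 at -1.80, succinyl-CoA:3-ketoacid transferase LinJ.33.2470 at 1.93) and 0.03 for oxidative phosphorylation (the last pair -0.16 and -0.19 with total-count scaling), each within its expression-matched random range.

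Stress, turnover and signalling lists had medians within their expression-matched random ranges, though the ubiquitin system, proteasome, autophagy, cysteine peptidase, sterol and aminoacyl-tRNA synthetase lists left theirs in some other settings. Heat shock protein 90 LinJ.29.0790 was at 2.15, a mitochondrial chaperone (LinJ.22.0760) at -1.44, and the 122 chaperone CDS had 11 higher and 11 lower. Among 44 redox genes, a tryparedoxin-like CDS (LinJ.29.1230), which has a tandem copy (LinJ.29.1220), was at 2.01. Iron superoxide dismutase A (LinJ.08.0300) was at 1.46 and ascorbate peroxidase (LinJ.34.0070) at -1.48. A calpain-like cysteine peptidase (LinJ.20.1320, 38023 and 21230 reads) was at 2.63. Of 15 autophagy CDS 6 were higher and none lower, the ATG8 copies at the top and ATG12 (LinJ.22.1120) at -0.75. The median of 0.39 (percentile 94.99) compares with a mean of 1.32 (percentile 100). That mean is raised by the 4 tandem copies of ATG8, at 3.62 to 4.64. Proteasome subunits had a median of 0.37 (percentile 96.7) with LinJ.02.0340, a regulatory non-ATPase subunit, at 2.34, and ubiquitin system genes -0.13. Of 165 protein kinases 12 were higher and 8 lower, from LinJ.11.0250 (2.86) to mitogen-activated protein kinase kinase 2 (LinJ.13.0280, -1.79). Squalene monooxygenase-like LinJ.13.1360, of sterol synthesis, was at 2.12. Translation factors had 10 higher and 5 lower of 84, and aminoacyl-tRNA synthetases 1 higher and 2 lower of 26. Alpha tubulin copies LinJ.13.1450 and LinJ.13.1460 were both at 0.95, and none of 14 tubulin list members or 7 tuzins was called.

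Whole chromosomes had shifted ratios, and 9 had a median of at least 0.3 in size outside the random range (1, 2, 5, 6, 8, 15, 20, 22 and 31), a set that depends on the scaling, since with total-count scaling 6, 20 and 31 dropped out and 19, 30 and 32 to 36 came in. Tandem arrays and gene families with a product name do not account for these shifts. Over CDS with a product name of their own, or with a hypothetical or unknown product, the median size of the shift was 0.44. The interval of each of the 9 medians stayed on its side of 0. Families among CDS without a known product were kept, so that their part was not tested. For the 8 chromosomes other than 1, neither does a small number of co-regulated stretches, because 119 of 126 windows of 10 genes (94.4%) had a median on the side of their chromosome. In the total-count set it was 341 of 361 for the 12 other than 1. Of these windows, 298 lie on the 7 chromosomes that came in with that scaling (279 on their side). As total-count scaling shifts all ratios down, those 298 windows do not bear on such stretches. On chromosome 1, 5 of 8 windows lay on its side (62.5%, exact 95% interval 24.5% to 91.5%), or 7 of 8 with total-count scaling. These are too few windows to exclude such stretches. A different copy number of whole chromosomes may be behind the shifts and stays open without DNA counts. It predicts that the first and second part of the genes of a chromosome, by gene order, shift alike. These parts differed in 1 of the 9 (chromosome 31, by -0.27, 95% interval -0.41 to -0.03). They differed in none of the 13 of the total-count set, of which 7 entered through that scaling alone. Scaling does not change this difference, so that the 6 chromosomes in both sets give the same result again. Chromosome 31 is not in the total-count set.

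The most extreme ratios often belonged to tandem copies, CDS of the same product name near each other, whose sequences were not compared. A candidate explanation is that reads were placed on another copy in the other library. It predicts that the sum over copies lies within 2-fold, as it did in 3 of 9 arrays: nucleoside transporter 1 (-0.32), the M17 peptidase (0.59) and HSP70-related protein 1 (-0.18). For HSP70-related protein 1 the extreme copy held few of the reads of its array. Its sum would lie within 2-fold whether or not reads had moved, so that it does not bear on this explanation. The sums of the other 6 stayed beyond 2-fold on the same side: microtubule associated protein-like (4.20), the 3-hydroxyisobutyryl-coenzyme A hydrolase-like protein (3.92), ATG8 (3.78), paraflagellar rod protein 1D (3.73), the P-type H-ATPase (-2.22) and L14 (-2.22). Read placement alone thus does not account for the difference of these arrays. The size of a single copy's ratio, such as 7.27 for a copy of paraflagellar rod protein 1D, may still depend on it. For nucleoside transporter 1 and the M17 peptidase, a switch between copies with distinct untranslated regions would look the same. No test here separates such a switch from read placement.

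HASP and SHERP mRNA was higher in sfPro, by over 4-fold for HASP and under 2-fold for SHERP. Extra copies of a stretch of chromosome 23 that holds these genes and their neighbours would raise the neighbours. The 20 flanking genes had a median of -0.27 (95% interval -0.46 to 0.37). This is below 1.0, which is 0.5 times the median of the 5 marker CDS there, and argues against such copies for HASP. For SHERP, which was under 2-fold, a bound set in this way would lie inside that interval, so that extra copies are not excluded. Extra copies of the marker genes alone would leave the flanking genes unchanged and were not tested. A larger share of metacyclic forms in the gut-derived pool may contribute and predicts that the metacyclic markers are higher. A bound of at least 2-fold for all of them, chosen after the results were seen, was met by 4 of 7. The abundant META domain CDS LinJ.17.0990 was at -2.0. A smaller rise of this share could leave markers under the bound. This share and a change within the cells cannot be told apart with 1 library per group.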
